A study of Mus musculus with 30 samples.

How the data were processed

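RNA-seq counts were analysed for 30 libraries of mouse satellite cells (C57BL/6, hind limb muscle), in 15 groups of 2. Per the labels, muscle was injured with barium chloride, mice were perfused with paraformaldehyde before the cells were isolated, and RNA was extracted with the miRNeasy FFPE kit. Polyadenylated RNA was the molecule, cDNA was made with SMART-Seq v4, libraries with Tn5, and sequencing was paired-end (2 × 100 cycles) on a DNBSEQ-G400. The authors' processing notes name Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 1.3 and StringTie 1.3.3 with the mm10 genome, without their order or settings. The program that counted reads, the strand it counted and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies can therefore be assigned to either gene.

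The authors deposited counts per gene in 3 tables, for the time course to 60 h (18 libraries), regeneration at 7, 14 and 28 days (6) and old cells (6). All values are whole numbers. The first 2 tables list the same 55450 gene identifiers, all of them in GENCODE M21. The table of old cells lists 55335, of which 54587 are in M21, so it was made with another release. Without version numbers 55154 identifiers matched over all tables, and 53086 with them. Library totals ranged from 9.18 to 57.4 M counts; no molecular identifiers are mentioned, so copies made by amplification are counted.

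Counts were fitted with edgeR 4.0.16 in R 4.3.3 (with data.table version 1.17.8 and limma 3.58.1). Genes passed filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM, and group means were compared with the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all genes tested in that comparison. Standard errors of log2 fold changes are the absolute change over the square root of F. There were 4 fits, the time course (22479 genes), regeneration (16954), old cells (30099), and all 30 libraries over matched identifiers (28823) for comparisons between tables. The comparisons are each time to 60 h with uninjured cells and any change over these 9 groups; 7, 14 and 28 days with uninjured cells; 14 and 28 with 7 days; oFISC and oASC with oQSC; oQSC with uninjured; oASC with 60 h; and the difference between the injury responses of old and younger cells. Common dispersions were 0.316, 0.432, 0.0878 and 0.316 in the 4 fits.

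For 30 lists of known genes (20 of pathways, 10 of marker genes of other cell types and of muscle fibres), members past the threshold were counted and the list was tested with fry on log2 CPM (prior count 2), adjusted over all lists and comparisons. The camera test with an estimated correlation between genes was the alternative. Unlike fry, it compares a list with the other genes. A call may thus fail there for that reason, and not only because of the correlation. Where the libraries of a group had no count, the fold was computed against a floor of 3 counts over the group's 2 libraries; this covers counting error only.

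Named genes came from a rule that took, for each comparison, the 6 largest rises and 6 largest falls among called genes with at least 20 CPM in the higher group and groups that do not overlap. It added up to 4 members with the smallest adjusted p of each list described, and a fixed panel of 25 genes. Unnamed gene models, mitochondrial and ribosomal protein genes were passed over. The groups, comparisons, tests, lists, this rule and all alternatives but those named as later additions in the closing section were chosen before the data were examined. The rule gave 1623 entries that were called, too many to print. The genes printed are a selection from them, made after their values and their calls under the alternatives were seen, so the printed genes hold up more often than the full set, for which the closing section gives counts. The lists printed were also selected in this way. The result for 1 gene is withheld and not reported here.

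The alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, leaving out each library in turn, other sets of libraries in the fit and, for the lists, camera. The tests were checked on simulated data with counts built from each fit's means and dispersions. Changes of 2, 4, 16 and 64-fold were called in 0%, 4%, 76% and 92% of genes for 0.5 h against uninjured cells. They were called in 0%, 30%, 64.6% and 79.2% for 28 against 7 days, 14%, 74%, 98% and 100% for oASC against oQSC cells, and 0%, 18%, 82% and 92% for oQSC against uninjured cells. False calls were 3 of 89, 13 of 97, 11 of 154 and 1 of 97. With 2 libraries per group, 2-fold changes were thus mostly missed in all 4 simulations, and 4-fold changes in all but that of the old cells. Only a small share of genes was changed there. That makes the adjusted threshold stricter than in comparisons where far more genes were called. These shares therefore do not measure what was missed in the data.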

Results

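RNA-seq counts were compared in satellite cells, the stem cells of skeletal muscle, isolated from C57BL/6 mice. Hind limbs had been injured with barium chloride, which destroys muscle fibres, and the animals were perfused with paraformaldehyde, a fixative, before the cells were isolated. The 30 libraries form 15 groups of 2. They are uninjured cells, cells taken 0.5, 1, 2, 4, 8, 16, 32 and 60 h after injury, cells taken 7, 14 and 28 days after injury, and 3 groups of old cells. The old groups are oQSC (fixed in place, no injury), oFISC and oASC (2.5 days after injury). The cells not labelled old are called younger here, although the labels give no ages. The labels of oFISC give both an injury treatment and the time "freshly isolated", so the state of these cells is uncertain. Nothing in the labels says that the libraries of a group come from separate animals, so errors and p-values reflect the spread between these samples only.

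Total counts were 13.5 and 21.4 M in the uninjured libraries and 21.7 to 36.8 M from 0.5 to 60 h. They were 9.59 and 9.18 M at 7 days, 11.3 and 12.4 M at 14 days, and 13.9 and 9.76 M at 28 days. The old groups held 44.8 and 47.2 M (oQSC), 21.1 and 23.3 M (oFISC), and 55.2 and 57.4 M (oASC). Gene models that overlap ribosomal RNA took 45.6% and 34.1% of the counts in the uninjured libraries and 26.5% and 29.1% at 60 h, but 3.53% to 9.53% from 0.5 to 32 h. Models of satellite repeats took 20.1% and 18.1% in oQSC and 58.6% and 25.4% in oFISC cells. Levels are in CPM, counts scaled to the library's total after TMM scaling, given as mean ± SD over the 2 libraries of a group.

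**Figure D1:**
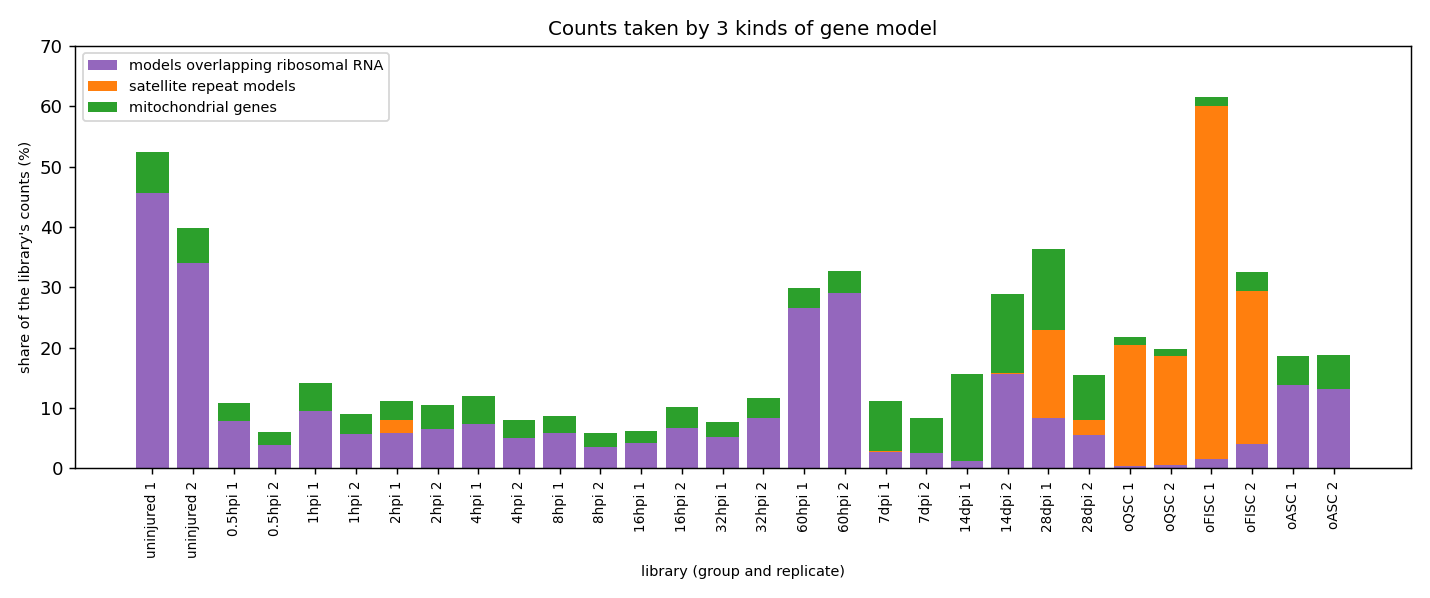
Share of each library's counts (%, stacked bars from 0) taken by models overlapping ribosomal RNA, satellite repeat models and mitochondrial genes, in the 30 libraries. The ribosomal RNA models reach 45.6% in uninjured 1, and the satellite repeat models 58.6% in oFISC 1.

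Libraries of a group were compared by Pearson's r of log2 CPM across the 2000 most variable genes, which are not independent replicates. It was 0.838 for the uninjured libraries, 0.947 at 8 h, 0.876 at 16 h, 0.833 at 32 h and 0.916 at 60 h. At 0.5, 1, 2 and 4 h it was 0.693, 0.816, 0.754 and 0.75, and each of these 8 libraries had its highest r with a library of another time. So did 16 h library 1, with an 8 h library (0.901), and 14 day library 1, with a 7 day library (0.648). Pax7, the transcription factor that marks satellite cells, and Myod1, which starts the myogenic programme, lay far apart inside these groups. Pax7 was at 756 and 135 CPM in libraries 1 and 2 of 0.5 h, 554 and 150 CPM at 1 h, 123 and 750 CPM at 2 h, and 987 and 69.9 CPM at 4 h. Myod1 was at 115 and 1520 CPM at 0.5 h, 159 and 1830 CPM at 1 h, 1980 and 81.8 CPM at 2 h, and 87.8 and 2170 CPM at 4 h. Among the later groups, r was 0.812 at 7 days, 0.634 at 14 days and 0.714 at 28 days, and 0.948, 0.899 and 0.964 in oQSC, oFISC and oASC cells.

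**Figure D2:**
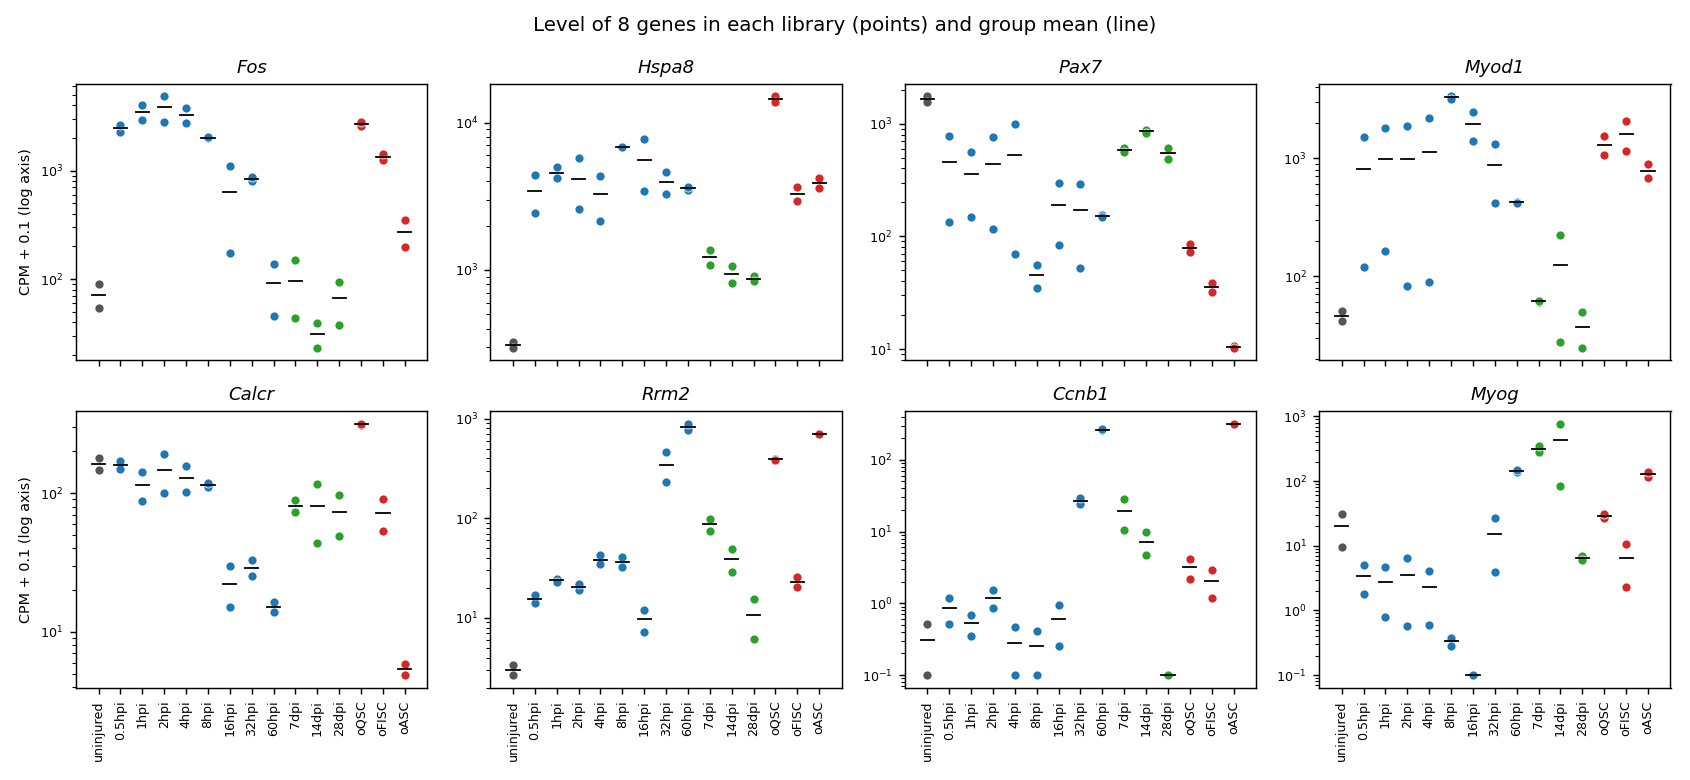
Level of 8 genes (CPM + 0.1, log axis, scaled over all 30 libraries) in each library (points), with the group mean (line), for the 15 groups. Pax7 and Myod1 lie apart inside the 0.5 to 4 h groups, Ccnb1 is high at 60 h and in oASC cells, and Rrm2 at 60 h and in oQSC and oASC cells.

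The series from 0.5 to 60 h asks how the transcriptome changes as satellite cells leave quiescence. At 0.5 h, genes that respond to stimuli without new protein synthesis were already higher than in uninjured cells. Fos was at 2430 ± 309 CPM against 73.1 ± 26.1 CPM (n = 2 per group; log2 fold change 5.05 ± 0.80, SE, adjusted p = 0.00413), Junb at 3100 ± 280 against 52.1 ± 4.99 CPM (5.89 ± 0.74), and Ier2 at 1470 ± 268 against 49.3 ± 4.27 CPM (4.89 ± 0.51). Socs3, a feedback inhibitor of cytokine signalling, rose by a log2 fold change of 5.62 ± 0.64, and the BMP targets Id1 and Id3 rose by 4.50 ± 0.48 and 3.84 ± 0.42. The chaperone Hspa8 rose from 315 ± 22.2 to 3400 ± 1480 CPM (3.43 ± 0.55, adjusted p = 0.0042). Rrad, a small GTPase, had no count in uninjured cells and was at least 531-fold higher at 0.5 h, against a floor of 3 counts over the group's 2 libraries. Notch1, a receptor of the pathway that keeps satellite cells quiescent, fell by 2.88 ± 0.34 on the log2 scale (adjusted p = 0.00125), from 772 ± 151 to 105 ± 2.07 CPM. The kinase Dyrk1b fell by 4.07 ± 0.54 and the imprinted gene Rtl1, whose reads cannot be told from those of its antisense partner without strand, fell by 4.08 ± 0.57. Lars2, which is not among the ribosomal RNA models left out in a later refit, fell by 4.61 ± 0.59. Whether its counts come from ribosomal RNA was not tested. Pax7 was at 445 ± 439 CPM against 1680 ± 149 CPM (adjusted p = 0.336).

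Among lists of known genes at 0.5 h, 18 of 25 immediate early and AP-1 genes rose and none fell (23 adjusted over the list alone; fry adjusted p = 0.000885), and 10 of 14 heat shock proteins rose (13 adjusted over the list alone; 0.00034). Neither call held (adjusted p = 0.337 and adjusted p = 0.256 with an estimated correlation). Of 12 BMP and Id genes, 5 rose (6 adjusted over the list alone; fry adjusted p = 2.93e-05, adjusted p = 0.239 with an estimated correlation). Of 22 NF-kB and cytokine response genes, 15 rose (18 adjusted over the list alone; fry adjusted p = 0.0341, adjusted p = 0.479 with an estimated correlation). Summed neutrophil markers were at 63.2 and 62.2 CPM against 2.29 and 2.99 CPM in uninjured cells, and fibro-adipogenic and fibroblast markers at 3690 and 1520 CPM against 1090 and 1190 CPM. Among genes with a wide spread, the chemokine Cxcl1 was at 5830 ± 7740 CPM against 20.9 ± 2 CPM (8.12 ± 1.72, adjusted p = 0.0134), and Jun, Atf3, the cell cycle inhibitor Cdkn1a and the chaperone gene Hspa1a, which has a near-identical copy, rose by log2 fold changes of 4.45 ± 0.90, 7.48 ± 1.55, 5.30 ± 1.11 and 6.97 ± 1.36. The edgeR quasi-likelihood test called 2315 of 22479 genes at 0.5 h, 1546 higher and 769 lower, with a median log2 fold change of all genes of 0.24. Of the 25 panel genes fixed beforehand, 10 rose and none fell. The count was 262 without uninjured 1, 627 without uninjured 2 and 690 without 0.5 h library 2. In that order the adjusted p became 0.117, 0.0979 and 0.0776 for Cxcl1 and 0.094, 0.0988 and 0.0831 for Cdkn1a, and no NF-kB gene was called. Without uninjured 1 or 2, it became 0.0704 or 0.0963 for Jun, 0.0955 or 0.101 for Atf3 and 0.107 or 0.068 for Hspa1a, with 5 or 7 immediate early genes and 2 heat shock proteins called in either case.

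From 1 to 4 h genes of the same kinds were higher than in uninjured cells. Fos was at 3490 ± 691, 3870 ± 1320 and 3270 ± 731 CPM at 1, 2 and 4 h (n = 2 per group; log2 fold changes 5.58 ± 0.82, 5.73 ± 0.83 and 5.48 ± 0.82, SE, adjusted p = 0.00271, 0.00285 and 0.00299). Socs3 rose by 5.64 ± 0.64, 5.91 ± 0.65 and 6.05 ± 0.66. Sphk1, a sphingosine kinase, rose from 0.328 ± 0.066 CPM to 61.3 ± 0.799 CPM at 2 h (7.56 ± 1.09) and 153 ± 41.2 CPM at 4 h (8.88 ± 1.14, adjusted p = 0.00151). Gdf15, a stress-induced cytokine, had no count in uninjured cells and was at least 288-fold higher at 1 h and at least 437-fold higher at 2 h. For Rrad the bounds were at least 503-fold at 1 h, at least 262-fold at 2 h and at least 408-fold at 4 h. Dyrk1b fell by 3.96 ± 0.54, 4.55 ± 0.55 and 4.50 ± 0.55 on the log2 scale. The chromatin remodeller Srcap fell by 3.92 ± 0.40 at 1 h (adjusted p = 0.000803). Of 25 immediate early and AP-1 genes, 22, 21 and 21 rose at 1, 2 and 4 h and none fell (25 at each time adjusted over the list alone). The list's fry adjusted p was 0.00034, 0.000372 and 0.000395, and adjusted p = 0.286, 0.286 and 0.305 with an estimated correlation. Pax7 was at 352 ± 285, 436 ± 444 and 529 ± 649 CPM (adjusted p = 0.265, 0.33 and 0.383). Myod1 was at 996 ± 1180, 1030 ± 1340 and 1130 ± 1480 CPM against 46.8 ± 6.38 CPM (adjusted p = 0.122, 0.121 and 0.105), after 817 ± 992 CPM at 0.5 h (adjusted p = 0.138). Without the filter on low counts its adjusted p was 0.00641, 0.0038, 0.00406 and 0.00282 at 0.5, 1, 2 and 4 h, and with DESeq2 it was 0.0174, 0.0109, 0.0103 and 0.00692.

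In all, 2295 genes were called at 1 h (1476 higher, 819 lower), 2092 at 2 h (1421 higher, 671 lower) and 2469 at 4 h (1614 higher, 855 lower). The median log2 fold change of all genes was 0.16, 0.18 and 0.17, and 0.07, 0.06 and 0.06 with RLE size factors. Of the 25 panel genes, 10, 9 and 11 rose at 1, 2 and 4 h and none fell. Markers of other cells moved with these genes at 1 and 4 h, and fewer of them at 2 h. Of 14 endothelial markers 9 rose at 1 h and 9 at 4 h (10 and 9 adjusted over the list alone; fry adjusted p = 0.00404 and 0.00739), and of 16 myofibre markers 8 and 8 (9 and 10, with 1 lower at 4 h, adjusted over the list alone; fry adjusted p = 0.000517 and 0.00048). With an estimated correlation none of these held (adjusted p = 0.426, 0.453, 0.286 and 0.305). At 2 h 1 of 14 endothelial and 3 of 16 myofibre markers rose (fry adjusted p = 0.25 and 0.0082, and 0.759 and 0.453 with an estimated correlation). Endothelial markers then summed to 133 and 142 CPM. At 1 h 2 of 8 lymphocyte markers rose (2 adjusted over the list alone; fry adjusted p = 6.51e-06, adjusted p = 0.0966 with an estimated correlation). Summed endothelial markers were at 506 and 325 CPM in the 1 h libraries and 248 and 527 CPM in the 4 h libraries, against 57.4 and 115 CPM in the uninjured ones. At 1 h the count was 377, 664, 1398 and 926 without uninjured 1, uninjured 2, 1 h library 1 and 1 h library 2. At 2 h it was 234, 529 and 473 without uninjured 1, uninjured 2 and 2 h library 1, and at 4 h it was 273, 578 and 520 without uninjured 1, uninjured 2 and 4 h library 2. Without uninjured 1 or uninjured 2, 10 or 9 immediate early genes were called at 1 h, and 6 in either case at 2 h and at 4 h. Endothelial markers were called in 0, 3 and 3 cases at 1 h without uninjured 1, uninjured 2 and 1 h library 1, and in 0, 2 and 2 cases at 4 h without uninjured 1, uninjured 2 and 4 h library 2. For myofibre markers it was 4, 3, 4 and 4 at 1 h (uninjured 1 and 2, 1 h library 1 and 2) and 4, 3 and 3 at 4 h (uninjured 1 and 2, 4 h library 2), and for lymphocyte markers 1 without uninjured 1 or 1 h library 2.

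At 8 h the cells had high Myod1 and low Pax7 in both libraries. Myod1 was at 3260 ± 83.5 CPM against 46.8 ± 6.38 CPM (n = 2 per group; log2 fold change 6.12 ± 1.88, SE, adjusted p = 0.0292), and Pax7 fell by 5.23 ± 1.44 on the log2 scale, from 1680 ± 149 to 44.8 ± 13.8 CPM (adjusted p = 0.0191). The growth regulator Myc was at 3010 ± 263 against 173 ± 3.26 CPM (4.12 ± 1.31, adjusted p = 0.0331). Of 25 ribosome biogenesis genes, 20 rose and none fell (23 adjusted over the list alone; fry adjusted p = 0.0287, adjusted p = 0.532 with an estimated correlation). One of them, Nop56, a part of the snoRNP that modifies ribosomal RNA, rose from 72.3 ± 13.5 to 1740 ± 179 CPM (4.59 ± 0.90, adjusted p = 0.00533). Fos, Socs3, Cdkn1a and Hspa8 were higher by 4.78 ± 0.79, 4.91 ± 0.62, 6.98 ± 1.20 and 4.43 ± 0.57, and the glycolytic enzyme Pgk1 by 2.33 ± 0.40. Immediate early and AP-1 genes rose in 21 of 25 cases and heat shock proteins in 12 of 14 (23 and 14 adjusted over the list alone; fry adjusted p = 0.000666 and 0.000189). Neither call held (adjusted p = 0.372 and adjusted p = 0.286 with an estimated correlation).

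Genes of quiescent satellite cells fell at 8 h. Of 18 genes of satellite cell identity and quiescence, 10 fell and 2 rose (the same numbers adjusted over the list alone; fry adjusted p = 0.00621, adjusted p = 0.468 with an estimated correlation). Notch1 fell by 2.89 ± 0.34 and Notch3 by 6.85 ± 1.10 on the log2 scale (adjusted p = 0.000908 and 0.00278), Notch3 from 1740 ± 139 to 15 ± 3.25 CPM (n = 2). The imprinted zinc finger gene Peg3 fell by 4.30 ± 0.63, the calcium release channel Ryr3 by 7.29 ± 1.24, and the matrix genes Frem1 and Hspg2 (perlecan) by 7.26 ± 1.31 and 3.82 ± 0.46. Dzip1, a gene of ciliary signalling, had no count at 8 h and was at least 397-fold lower than in uninjured cells. Summed markers of pericytes and smooth muscle, another source of Notch3, were at 119 and 90.9 CPM in the 8 h libraries against 1620 and 1790 CPM in the uninjured ones. Within that list 3 of 12 markers rose and 2 fell (fry adjusted p = 0.729), so the sum does not stand for the list. Of 14 endothelial markers 8 rose, and of 16 myofibre markers 8 rose and 2 fell (9, 9 and 2 adjusted over the list alone; fry adjusted p = 0.0226 and 0.00621). Neither call held (adjusted p = 0.519 and adjusted p = 0.468 with an estimated correlation). In all 6756 genes were called, 3610 higher and 3146 lower (3302 and 3397 with RLE size factors), and 14 of the 25 panel genes rose and 3 fell. The count was 2077, 2628, 2250 and 1986 without uninjured 1, uninjured 2, 8 h library 1 and 8 h library 2. In that order the adjusted p became 0.143, 0.132, 0.0706 and 0.0719 for Myod1, 0.0624, 0.0546, 0.102 and 0.132 for Pax7, and 0.142, 0.141, 0.0766 and 0.0875 for Myc. Also in that order, 1, 2, 4 and 4 ribosome biogenesis genes rose and 2, 3, 1 and 1 identity genes fell, while 5 and 6 heat shock proteins rose without uninjured 1 and 2, and 11 immediate early genes without uninjured 2. Endothelial markers rose in 2 and 3 cases without uninjured 1 and 8 h library 1, and myofibre markers in 5 and 3 without uninjured 2 and 8 h library 1.

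At 16 h oxidative phosphorylation genes were higher, as some were from 0.5 h on, and Calcr and Notch1 were lower. Of 22 oxidative phosphorylation genes 4, 6, 6, 7 and 9 rose at 0.5, 1, 2, 4 and 8 h, and 1 fell at 8 h. At these times the list's fry adjusted p was 0.000133, 0.000538, 0.000164, 0.000133 and 0.000234. With an estimated correlation it was 0.286, 0.337, 0.286, 0.286 and 0.347. The calcitonin receptor Calcr, a receptor of quiescent satellite cells, fell by 2.87 ± 0.43 on the log2 scale (SE), from 166 ± 22.5 to 22.7 ± 10.6 CPM (n = 2 per group; adjusted p = 0.00158). Tenm4, Peg3 and Ryr3 fell by 4.68 ± 0.69, 3.22 ± 0.60 and 9.24 ± 1.34, Notch1 by 3.50 ± 0.35 (adjusted p = 0.000501), and the basement membrane genes Col15a1 and Hspg2 by 9.86 ± 1.45 and 2.91 ± 0.44. Asns, the enzyme that makes asparagine, had no count in uninjured cells and was at least 306-fold higher at 16 h. The replication gene Mcm5 rose from 2.77 ± 1.26 to 27.3 ± 5.2 CPM (3.32 ± 0.62, adjusted p = 0.00413) and the respiratory chain gene Uqcrc2 from 33.4 ± 0.201 to 150 ± 21.3 CPM (2.17 ± 0.30, adjusted p = 0.00109). Fos was at 657 ± 678 CPM (3.17 ± 0.73, adjusted p = 0.0105). Myog, which drives myoblast differentiation, had no count at 16 h and was at least 470-fold lower than the 20.7 ± 15.9 CPM of uninjured cells (adjusted p = 0.00636). Its fitted log2 fold change was -12.09, and -11.01 without uninjured 1. Of 22 oxidative phosphorylation genes, 17 rose and none fell (18 adjusted over the list alone; fry adjusted p = 1.07e-05, adjusted p = 0.181 with an estimated correlation). Of 18 basement membrane and collagen genes, 7 fell and 3 rose (8 and 3 adjusted over the list alone). The list's fry adjusted p was 0.00235 (adjusted p = 0.44 with an estimated correlation). Summed pericyte and smooth muscle markers were at 95.3 and 149 CPM against 1620 and 1790 CPM in uninjured cells. Within that list 3 of 12 markers fell and 2 rose (fry adjusted p = 0.451).

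The test called 5096 genes at 16 h, 3186 higher and 1910 lower, and 9 of the 25 panel genes rose and 4 fell. The median log2 fold change of all genes was 0.11, and -0.03 with RLE size factors, which gave 2491 higher and 2307 lower genes and 11 oxidative phosphorylation genes; DESeq2 gave 3731 higher and 3579 lower genes. Without uninjured 1, uninjured 2, 16 h library 1 and 16 h library 2 the count was 1487, 1956, 1215 and 2824, and 5, 8, 6 and 11 oxidative phosphorylation genes rose. The adjusted p for Fos was 0.0592, 0.0927 and 0.205 without uninjured 1, uninjured 2 and 16 h library 1, and for Myog 0.0546 without 16 h library 1.

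At 32 h genes of DNA replication and mitosis were higher. Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, rose from 2.95 ± 0.467 to 354 ± 177 CPM (n = 2 per group; log2 fold change 6.89 ± 0.49, SE, adjusted p = 7.88e-05). The helicase genes Mcm5 and Mcm4 rose by 6.04 ± 0.70 and 4.44 ± 0.40, the topoisomerase gene Top2a by 6.23 ± 0.58, and cyclin A2 (Ccna2) by 5.01 ± 0.50 (adjusted p = 0.000529, 0.000189, 0.000189 and 0.00026). Of 26 genes of S phase and DNA replication, 25 rose (25 adjusted over the list alone; fry adjusted p = 2.53e-06, adjusted p = 0.0966 with an estimated correlation). Of 22 genes of G2 and mitosis, 21 rose (21 adjusted over the list alone; fry adjusted p = 1.5e-07), a call that held with an estimated correlation (adjusted p = 0.0115). Mki67 was at 58.8 ± 2.23 CPM against 11.3 ± 9.81 CPM (adjusted p = 0.154, and 0.0366 without the filter on low counts). Calcr fell by 2.50 ± 0.43 (adjusted p = 0.00245), and the respiratory gene Atp5a1 and the glycolytic gene Pgk1 rose by 2.03 ± 0.33 and 2.99 ± 0.41. Of 16 macrophage and monocyte markers, 11 rose (16 adjusted over the list alone; fry adjusted p = 0.00347, adjusted p = 0.453 with an estimated correlation). Of 14 endothelial markers 8 rose (10 rose and 1 fell adjusted over the list alone; fry adjusted p = 0.0116, adjusted p = 0.503 with an estimated correlation). The macrophage markers summed to 150 and 860 CPM in the 32 h libraries against 6.59 and 4.35 CPM in the uninjured ones. Lyz2 was at 202 ± 232 CPM (7.37 ± 1.56, adjusted p = 0.00705), and Arg1, Ccl6 and Ctss, with no count in uninjured cells, were at least 343-fold, at least 563-fold and at least 343-fold higher. These rises lean on 32 h library 2. The fitted log2 fold changes of Arg1, Ccl6 and Ctss were 12.74, 13.45 and 12.74 with it. Without it they were 12, 11.73 and 10.34, and that of Lyz2 was 4.88.

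The test called 4616 genes at 32 h, 3169 higher and 1447 lower, and 12 of the 25 panel genes rose and 3 fell. The median log2 fold change of all genes was 0.25, and 0.01 with RLE size factors, which gave 2471 higher and 1801 lower genes and 7 macrophage markers; DESeq2 gave 3748 higher and 3070 lower genes. Without uninjured 1, uninjured 2, 32 h library 1 and 32 h library 2 the count was 1510, 1830, 1480 and 2984, and 4, 1, 3 and 3 macrophage markers rose. Endothelial markers rose in 2 and 3 cases without uninjured 1 and 32 h library 1. The adjusted p for Lyz2 was 0.0566 and 0.073 without uninjured 1 and 2, and for Ctss 0.055 without uninjured 2. Without the ribosomal RNA, satellite repeat and mitochondrial models, 7 macrophage markers rose.

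At 60 h both lists of proliferation genes were higher and the replicates lay close together. Rrm2 was at 837 ± 83.2 CPM against 2.95 ± 0.467 CPM (n = 2 per group; log2 fold change 8.14 ± 0.51, SE, adjusted p = 1e-05) and cyclin B1 (Ccnb1) at 267 ± 2.94 against 0.211 ± 0.299 CPM (10.01 ± 1.45, adjusted p = 0.000562). Mcm5, Ccna2 and Top2a rose by 6.74 ± 0.72, 6.82 ± 0.54 and 6.74 ± 0.59. The mitotic kinase gene Aurka and the cell cycle regulator E2f7 had no count in uninjured cells and were at least 1090-fold and at least 781-fold higher. Of 26 genes of S phase and DNA replication, 25 rose (25 adjusted over the list alone; fry adjusted p = 1.55e-06, adjusted p = 0.0966 with an estimated correlation). All 22 genes of G2 and mitosis rose (22 adjusted over the list alone; fry adjusted p = 2.48e-08), a call that held with an estimated correlation (adjusted p = 0.00897). Mki67 was at 193 ± 18.7 CPM (4.11 ± 1.24, adjusted p = 0.0266). Energy genes rose as well, with Uqcrc1 and Sdhb of the respiratory chain higher by 2.75 ± 0.33 and 2.65 ± 0.35 and the glycolytic gene Eno1 at 2910 ± 12.6 against 195 ± 8.64 CPM (3.90 ± 0.40, adjusted p = 9.79e-05). Of 22 oxidative phosphorylation genes 21 rose, and of 18 glycolysis genes 11 rose (21 and 11 adjusted over the list alone; fry adjusted p = 6.98e-07 and 3.62e-05). These were adjusted p = 0.0966 and adjusted p = 0.325 with an estimated correlation.

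Of 17 genes of myogenic commitment and differentiation, 6 rose at 60 h (6 adjusted over the list alone, 10 without the filter on low counts; fry adjusted p = 0.000334, adjusted p = 0.325 with an estimated correlation). Among single genes of muscle fibres and their synapses, the acetylcholine receptor subunits Chrna1 and Chrng were higher by 4.07 ± 0.83 and 7.59 ± 1.51 (adjusted p = 0.00392 and 0.00339; n = 2) and Acta1, the actin of muscle fibres, by 3.63 ± 0.99 (adjusted p = 0.0165). Of 18 genes of satellite cell identity and quiescence, 7 fell and 2 rose (9 and 2 adjusted over the list alone; fry adjusted p = 0.00154, adjusted p = 0.468 with an estimated correlation). Calcr fell by 3.44 ± 0.44, Spry1, an inhibitor of growth factor signalling, by 3.18 ± 0.45, Chrdl2 by 4.41 ± 0.32, Notch1 by 1.71 ± 0.32 and the adenylyl cyclase gene Adcy2 by 6.01 ± 0.71 on the log2 scale. Pax7 was at 153 ± 5.23 against 1680 ± 149 CPM (adjusted p = 0.068, 0.00193 without the filter on low counts and 0.00652 with DESeq2). Of 18 basement membrane and collagen genes, 10 fell and 3 rose (10 and 4 adjusted over the list alone; fry adjusted p = 0.0027, adjusted p = 0.467 with an estimated correlation), while summed pericyte and smooth muscle markers were at 265 and 239 CPM against 1620 and 1790 CPM in uninjured cells. Among these 12 markers 5 fell and 1 rose (fry adjusted p = 0.0746). Of 16 macrophage and monocyte markers, 10 rose (13 adjusted over the list alone; fry adjusted p = 0.00699, adjusted p = 0.467 with an estimated correlation), with summed levels of 270 and 55.3 CPM in the libraries. Of 25 immediate early and AP-1 genes, 6 rose and 1 fell (the same numbers adjusted over the list alone; fry adjusted p = 0.176). The test called 6354 genes, 3476 higher and 2878 lower (3134 and 3212 with RLE size factors), and 8 of the 25 panel genes rose and 3 fell. Without uninjured 1, uninjured 2, 60 h library 1 and 60 h library 2 the count was 3414, 3475, 3443 and 3248, the adjusted p for Mki67 was 0.0595, 0.164, 0.0656 and 0.0783, and 4, 2, 2 and 5 macrophage markers rose. Basement membrane genes fell in 5 and 6 cases without 60 h library 1 and 2, 1, 2 and 1 immediate early genes rose without uninjured 1, uninjured 2 and 60 h library 2, and Acta1 had an adjusted p of 0.0638 without 60 h library 2.

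Over the 9 groups from uninjured to 60 h, edgeR's quasi-likelihood test of any change, on 8 coefficients together, called 5561 of 22479 genes. That is fewer than the 6756 called at 8 h alone or the 6354 at 60 h alone. So this count is not the total of genes that changed at some time. The count was 3051 and 3214 without uninjured 1 and 2, 3635 and 3647 without 8 h library 1 and 2, and 2847 and 2835 without 60 h library 1 and 2. The tests of gene lists with fry ask whether the genes of a list move, on balance, one way, and do not compare the list with other genes. Of 538 such tests over 30 lists and 18 comparisons, 265 had an adjusted p under 0.05. The alternative with an estimated correlation between genes (camera) does compare a list with other genes, so it asks a different question. With it 4 of these 265 held, for G2 and mitosis at 32 h, 60 h and 7 days and for S phase and DNA replication at 7 days.

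**Figure D3:**
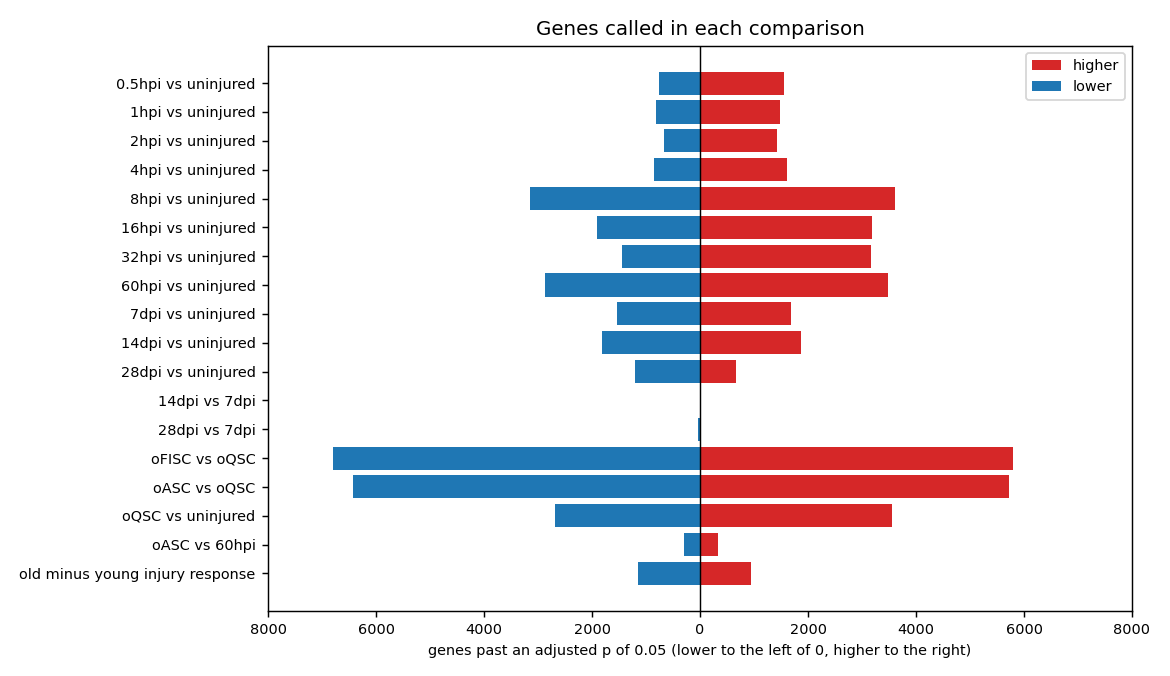
Genes past an adjusted p of 0.05 in each of the 18 comparisons, higher to the right of 0 and lower to the left (bars, number of genes). The old cells inside their own table show the most calls (12607 for oFISC against oQSC cells), and 14 against 7 days the fewest (9).

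**Figure D4:**
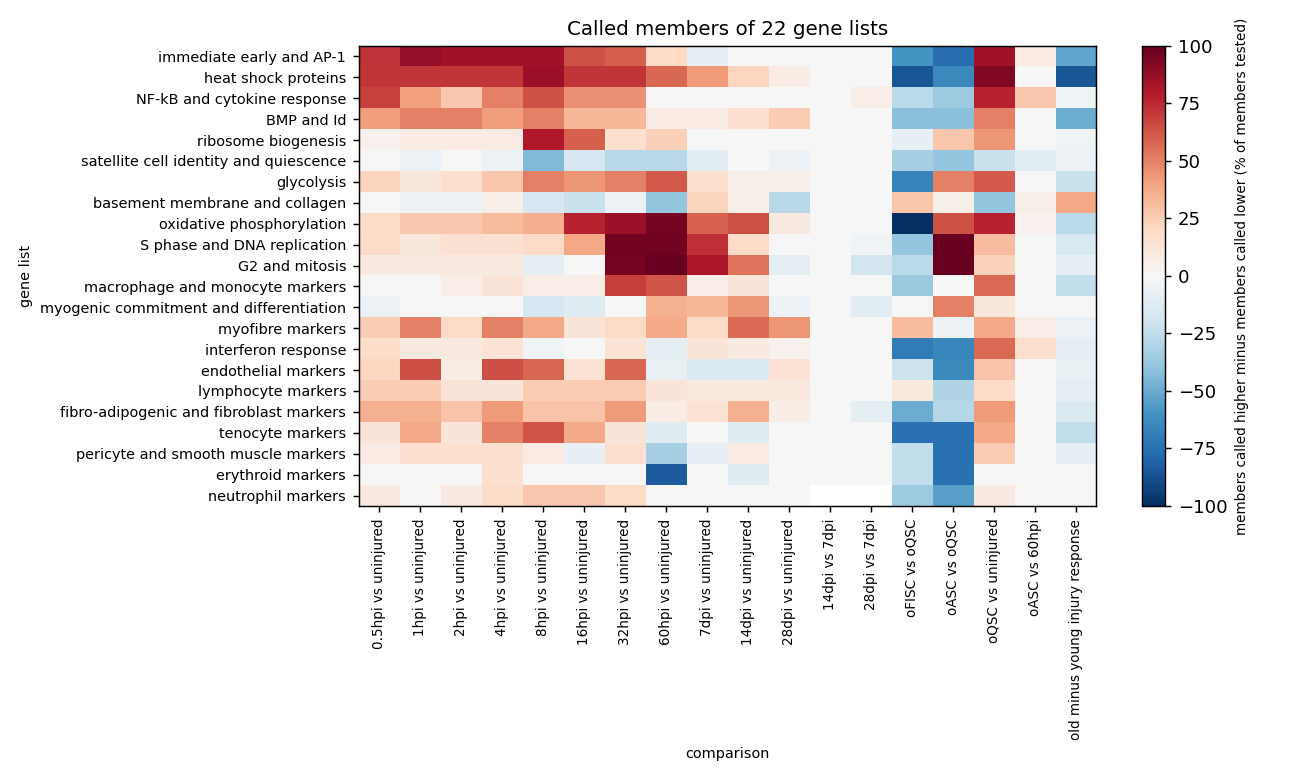
Members of 22 gene lists called higher minus members called lower, as % of the members tested (colour), in the 18 comparisons (neutrophil markers were not tested for 14 and 28 against 7 days). Every member of the G2 and mitosis list was called higher at 60 h (22 of 22) and in oASC against oQSC cells (22 of 22).

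The later series asks how cells change while muscle regenerates. At 7 days cell cycle genes were higher than in uninjured cells. Rrm2 was at 86.6 ± 16.5 against 2.91 ± 0.482 CPM (n = 2 per group; log2 fold change 4.88 ± 0.47, SE, adjusted p = 1.58e-06), and Mcm5, Top2a and Ccnb1 rose by 3.66 ± 0.54, 6.49 ± 0.85 and 6.24 ± 1.15. Of 26 genes of S phase and DNA replication 19 rose, and of 22 genes of G2 and mitosis 18 rose (22 and 21 adjusted over the list alone; fry adjusted p = 1.64e-07 and 5.82e-07). Both calls held with an estimated correlation (adjusted p = 0.0127 and adjusted p = 0.0287). Of 18 genes of myogenic commitment and differentiation, 6 rose (11 adjusted over the list alone; fry adjusted p = 5.33e-06, adjusted p = 0.0966 with an estimated correlation). Mymx, which drives myoblast fusion, had no count in uninjured cells and was at least 294-fold higher, Tnnt2, a troponin of immature muscle, rose by 7.99 ± 1.28, and Myog was at 311 ± 46.8 against 20.3 ± 15.5 CPM (3.94 ± 1.24, adjusted p = 0.045). The proteoglycan Gpc3 rose from 0.394 ± 0.167 to 255 ± 25.4 CPM (9.26 ± 0.93, adjusted p = 2.44e-06) and the collagen gene Col5a2 rose by 2.13 ± 0.32, while Chrdl2, Srcap, Tnxb and Hspg2 fell by 2.79 ± 0.43, 5.90 ± 0.51, 7.23 ± 0.74 and 2.87 ± 0.44 on the log2 scale. Summed fibro-adipogenic and fibroblast markers were at 3870 and 3470 CPM at 7 days against 1090 and 1190 CPM. Pax7 was at 579 ± 36.2 against 1650 ± 135 CPM (adjusted p = 0.361, 0.00923 without the filter on low counts and 0.00165 with only these groups fitted).

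The test called 3226 of 28823 genes at 7 days, 1684 higher and 1542 lower (1374 and 1793 with RLE size factors, 2377 and 2920 with DESeq2), and 4 of the 25 panel genes rose and 1 fell. These cells and the uninjured ones are counted in separate tables, so a difference between the tables is part of each such result. Without uninjured 1, uninjured 2, 7 day library 1 and 7 day library 2 the count was 1340, 1354, 1468 and 1192, and the adjusted p for Myog was 0.127, 0.324, 0.116 and 0.167. The call on Myog also ended with RLE size factors (0.0538), with the replicate number as a block (0.141) and without the ribosomal RNA, satellite repeat and mitochondrial models (0.0512). Without uninjured 2, 10 S phase, 11 mitosis and 3 myogenic genes rose, and without 7 day library 1, 12 S phase genes rose. With only these groups fitted, or without the filter on low counts, 10 myogenic genes rose.

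At 14 days genes of muscle fibres were higher. Mymx was at least 235-fold higher than in uninjured cells, and the troponin genes Tnnt2 and Tnnc2 rose by 7.73 ± 1.27 and 5.59 ± 1.01 (log2, SE, n = 2 per group; adjusted p = 0.000602 and 0.00126). Of 16 myofibre markers 9 rose, of 18 myogenic genes 8 rose, and of 22 genes of G2 and mitosis 12 rose (9, 11 and 16 adjusted over the list alone; fry adjusted p = 0.00347, 1.24e-05 and 0.000119). These were adjusted p = 0.372, adjusted p = 0.121 and adjusted p = 0.173 with an estimated correlation. Myf5, a myogenic factor of committed satellite cells, was at 1670 ± 896 against 309 ± 176 CPM (2.43 ± 0.67, adjusted p = 0.019), the mitotic gene Ube2c rose by 4.41 ± 0.85 (adjusted p = 0.00194), and Ankrd52 and the GABA receptor subunit Gabre fell by 5.51 ± 0.50 and 5.82 ± 0.92 on the log2 scale. Pax7 was at 851 ± 28.5 CPM (adjusted p = 0.586). In all 3700 genes were called, 1876 higher and 1824 lower (1524 and 2129 with RLE size factors, 2503 and 3333 with DESeq2), with 5 panel genes higher and 1 lower. Without uninjured 1 and 2 the count was 1479 and 1541 and the adjusted p for Myf5 0.265 and 0.0718; it was 0.218 without 14 day library 1, and 0.0708 for Ube2c without uninjured 2. Without uninjured 1 or 2, 5 or 4 myofibre markers rose, and without uninjured 2 or 14 day library 2, 2 or 3 myogenic genes and 4 or 7 mitosis genes. With only these groups fitted edgeR called 0 genes (4690 at an unadjusted p under 0.05), and the adjusted p was 0.0525 for Mymx, 0.0638 for Tnnt2, 0.0552 for Tnnc2, 0.0517 for Ankrd52 and Gabre, 0.0783 for Myf5 and 0.0649 for Ube2c; with the replicate number as a block, 3 myogenic genes rose.

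At 28 days matrix genes were among the genes that fell against uninjured cells. Hspg2 and the laminin gene Lamc1 fell by 3.49 ± 0.46 and 2.05 ± 0.32 on the log2 scale (SE, n = 2 per group; adjusted p = 0.000111 and 0.000586), Hspg2 from 636 ± 75.4 to 56.7 ± 16.7 CPM. Of 18 basement membrane and collagen genes, 7 fell and 2 rose (9 and 2 adjusted over the list alone; fry adjusted p = 0.00438, adjusted p = 0.453 with an estimated correlation). Of 16 myofibre markers 7 rose (8 rose and 1 fell adjusted over the list alone; fry adjusted p = 0.0101, adjusted p = 0.411 with an estimated correlation). Pericyte and smooth muscle markers, cells that also make basement membrane, summed to 388 and 474 CPM against 1620 and 1790 CPM. This sum does not stand for the list, in which 1 of 12 markers rose and 1 fell. Adjusted over the list alone 3 rose and 1 fell (median log2 fold change 0.72, fry adjusted p = 0.575). The chemokine gene Ccl11 rose by 4.36 ± 0.67 (adjusted p = 0.000559) and Acsf2 fell by 5.93 ± 1.05. Pax7 was at 545 ± 80.7 CPM (adjusted p = 0.354, 0.00899 without the filter on low counts and 0.0243 with only these groups fitted). The test called 1872 genes, 660 higher and 1212 lower, with 1 panel gene higher and 1 lower. With only these groups fitted it called 1915, against 0 at 14 days. The count was 618, 695 and 494 without uninjured 1, uninjured 2 and 28 day library 1, and 4 and 2 basement membrane genes fell without uninjured 1 and 28 day library 1. Myofibre markers rose in 3, 2 and 0 cases without uninjured 1, uninjured 2 and 28 day library 1, and in 2, with 1 lower, with only these groups fitted.

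Inside the regeneration series few genes passed the test between times. From 7 to 28 days the cell cycle genes Top2a and Mki67 fell by 8.14 ± 1.13 and 5.52 ± 0.60 on the log2 scale (SE, n = 2 per group; adjusted p = 0.0475 and 0.0335), and the cell cycle inhibitor Cdkn1c by 5.10 ± 0.38, from 604 ± 58.7 to 17.6 ± 0.309 CPM (adjusted p = 0.0276). Actc1, the cardiac actin that immature muscle also makes, had no count at 28 days and was at least 687-fold lower (adjusted p = 0.0403), and the clock gene Nr1d1 rose by 3.49 ± 0.39 (adjusted p = 0.0364). Of 22 genes of G2 and mitosis 4 fell and of 26 genes of S phase and DNA replication 1 fell (19 and 17 adjusted over the list alone; fry adjusted p = 0.00986 and 0.00194). Neither call held (adjusted p = 0.326 and adjusted p = 0.158 with an estimated correlation). From 7 to 14 days Postn, a matrix protein of healing tissue, fell by 4.55 ± 0.44 (adjusted p = 0.0392), from 101 ± 20.8 to 4.32 ± 1.1 CPM. Summed fibro-adipogenic and fibroblast markers were at 3870 and 3470 CPM at 7 days, 2980 and 2080 CPM at 14 days and 1230 and 1840 CPM at 28 days, and endothelial markers at 41.6 and 45.7, 79.2 and 51, and 322 and 160 CPM. The test called 50 of 16954 genes from 7 to 28 days (14 higher, 36 lower) and 9 from 7 to 14 days (8 higher, 1 lower), and DESeq2 called 1213 (481 higher, 732 lower) and 605 (323 higher, 282 lower). All 8 genes that edgeR called higher at 14 days are unnamed gene models or the pseudogene Gapdh-ps15, whose reads may come from near-identical copies. Leaving out 28 day library 1, 28 day library 2, 7 day library 1 or 7 day library 2 left 0 calls by edgeR from 7 to 28 days (1195, 2307, 1271 and 1051 genes at an unadjusted p under 0.05), with adjusted p-values of 0.0724 to 0.34 for these genes. From 7 to 14 days there were 0 calls without 7 day library 1 or 2 (836 and 746 at an unadjusted p under 0.05), 324 without 14 day library 1 and 26 without 14 day library 2, and for Postn the adjusted p was 0.585 and 0.399 without 7 day library 1 and 2 and 0.0604 with the replicate number as a block.

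Old cells 2.5 days after injury were compared with old cells fixed without injury inside the same table. Genes of the cell cycle were higher after injury. Mcm2 was at 330 ± 4.67 CPM in oASC and 5.34 ± 1.12 CPM in oQSC cells (n = 2 per group; log2 fold change 5.95 ± 0.26, SE, adjusted p = 6.16e-06), the mitotic kinase gene Plk1 at 128 ± 4.93 and 0.519 ± 0.0867 CPM (7.93 ± 0.27), and Mcm5, Ccnb1 and Mki67 rose by 5.45 ± 0.25, 6.68 ± 0.47 and 5.99 ± 0.44. All 26 genes of S phase and DNA replication and all 22 of G2 and mitosis rose (26 and 22 adjusted over the list alone; fry adjusted p = 8.44e-05 and 0.000904). These were adjusted p = 0.121 and adjusted p = 0.326 with an estimated correlation. Of 18 genes of satellite cell identity and quiescence, 12 fell and 5 rose (the same numbers adjusted over the list alone; fry adjusted p = 0.00146, adjusted p = 0.46 with an estimated correlation). Calcr, Chodl and Chrdl2 fell by 5.90 ± 0.31, 7.20 ± 0.32 and 5.55 ± 0.40 on the log2 scale, and Pax7 by 2.93 ± 0.21, from 67.6 ± 8.48 to 8.85 ± 0.25 CPM (adjusted p = 2.46e-05). The Notch ligand Dll1 rose from 3.5 ± 1.62 to 84.4 ± 18.7 CPM (4.59 ± 0.37). Of 25 immediate early and AP-1 genes, 20 fell and 1 rose (21 and 1 adjusted over the list alone; fry adjusted p = 0.00122, adjusted p = 0.325 with an estimated correlation), Fos by 3.32 ± 0.33 and the antiproliferative gene Btg2 by 6.20 ± 0.29, and Hspa1a fell by 4.80 ± 0.45. Of 23 interferon response genes, 17 fell and 2 rose (18 and 2 adjusted over the list alone; fry adjusted p = 0.000541, adjusted p = 0.261 with an estimated correlation). Markers of several other cell types fell with them. Those of macrophages and monocytes (3 of 16 rose and 3 fell) and of myofibres (1 of 16 rose and 2 fell) did not (fry adjusted p = 0.927 and 0.912). Tenocyte markers fell in 7 of 8 cases and rose in 1, pericyte and smooth muscle markers fell in 9 of 12, endothelial markers fell in 10 of 14 and rose in 1, erythroid markers fell in 6 of 8 and neutrophil markers in 6 of 11. In the same order the falls were 7, 9, 11, 6 and 7 adjusted over the list alone, with 1 rise each for the first 3. The fry adjusted p was 0.00868, 0.00607, 0.0341, 0.00412 and 0.00921, and adjusted p = 0.479, 0.477, 0.587, 0.468 and 0.489 with an estimated correlation. The test called 12137 of 30099 genes, 5715 higher and 6422 lower, with a median log2 fold change of all genes of -0.33, and 5 panel genes rose and 15 fell. With all 30 libraries in the fit the count was 4972 (2837 higher, 2135 lower), 13 immediate early genes fell, 4 pericyte, 3 endothelial and 1 neutrophil markers fell, and the adjusted p for Pax7 was 0.0565.

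In oFISC cells, whose labels conflict, genes of stress and of respiration were among those lower than in oQSC cells. Hspa8 fell by 2.52 ± 0.31 on the log2 scale (SE), from 12400 ± 1110 to 2160 ± 419 CPM (n = 2 per group; adjusted p = 0.000418), and Btg2 and the phosphatase gene Dusp1 by 3.21 ± 0.25 and 2.88 ± 0.32. All 22 oxidative phosphorylation genes fell (22 adjusted over the list alone; fry adjusted p = 0.00257, adjusted p = 0.453 with an estimated correlation), with Ndufb8 and Sdhb lower by 3.34 ± 0.26 and 2.93 ± 0.23 on the log2 scale. Of 14 heat shock proteins 12 fell, and of 25 immediate early and AP-1 genes 17 fell and 2 rose (12, 18 and 2 adjusted over the list alone; fry adjusted p = 0.00191 and 0.00583). These were adjusted p = 0.337 and adjusted p = 0.343 with an estimated correlation. The fall was wider than these lists. Of 26 S phase and DNA replication genes 12 fell and 2 rose. Of 18 glycolysis genes 12 fell, and of 23 interferon response genes 16 fell. In that order the fry adjusted p was 0.00146, 0.00577 and 0.00122 (0.325, 0.453 and 0.239 with an estimated correlation). Of 18 basement membrane and collagen genes 6 rose and 1 fell (fry adjusted p = 0.177). The satellite cell genes Cd34, Chodl, Calcr and Pax7 fell by 2.71 ± 0.20, 3.01 ± 0.26, 2.52 ± 0.27 and 1.56 ± 0.20. In oQSC and oFISC libraries summed macrophage markers were at 136 and 120 against 35.3 and 35.5 CPM, Schwann cell markers at 397 and 408 against 81.4 and 78.7 CPM, erythroid markers at 165 and 162 against 34.5 and 35.7 CPM, and tenocyte markers at 90.6 and 112 against 33.9 and 25.2 CPM. The Schwann cell sum does not stand for its list, as only 3 of 10 markers fell (median log2 fold change -0.25, fry adjusted p = 0.108). Falls were called for 9 of 16 macrophage, 4 of 8 erythroid and 6 of 8 tenocyte markers, and rises for 3, 2 and 0. Their fry adjusted p was 0.0178, 0.0338 and 0.07. Hmox1, which breaks down haem, rose from 130 ± 2 to 1060 ± 332 CPM (3.02 ± 0.46, adjusted p = 0.00128), and Cebpb and the Hippo kinase gene Lats1 rose by 2.86 ± 0.30 and 3.07 ± 0.29. The oFISC libraries had counts for 42760 and 45441 genes against 32426 and 33658 in the deeper oQSC libraries, and 975 and 1150 CPM over olfactory receptor genes against 127 and 117 CPM. Whether this spread of counts over more genes contributes to the falls above was not tested. The test called 12607 genes, 5803 higher and 6804 lower, with a median log2 fold change of all genes of 0.52; with RLE size factors the median was 0.81 and 7480 genes were higher and 5697 lower. Of the panel genes 2 rose and 15 fell. The count was 8000 and 8258 without oFISC 1 and 2. With all 30 libraries in the fit it was 2440 (566 higher, 1874 lower), with 3 immediate early genes and 3 heat shock proteins lower and adjusted p-values of 0.436 for Pax7 and 0.266 for Hmox1.

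Old and younger uninjured cells, both fixed in place, differed in stress genes. Hspa8 was at 14400 ± 1000 CPM in oQSC and 310 ± 19.5 CPM in uninjured cells (n = 2 per group; log2 fold change 5.54 ± 0.52, SE, adjusted p = 1.19e-06), Hspb1, a small heat shock protein, at 3600 ± 446 and 18.4 ± 1.63 CPM (7.61 ± 1.00), and Fos at 2720 ± 172 and 71.9 ± 25.1 CPM (5.24 ± 0.80, adjusted p = 8.15e-05). Btg2, Atf3, Cdkn1a, Socs3 and the NF-kB inhibitor Nfkbia rose by 5.77 ± 0.86, 8.45 ± 1.53, 7.27 ± 1.02, 4.12 ± 0.64 and 4.88 ± 0.75. Of 25 immediate early and AP-1 genes 21 were higher, of 14 heat shock proteins 13 and of 23 interferon response genes 13, with none lower (24, 13 and 16 adjusted over the list alone; fry adjusted p = 3.37e-05, 1.5e-07 and 2.04e-05). These were adjusted p = 0.342, adjusted p = 0.158 and adjusted p = 0.325 with an estimated correlation. Of 22 oxidative phosphorylation genes 17 were higher (18 adjusted over the list alone; fry adjusted p = 2.23e-06, adjusted p = 0.337 with an estimated correlation), Uqcrc1 by 2.70 ± 0.32. The cytokine gene Il33 and Rrad had no count in uninjured cells and were at least 1380-fold and at least 811-fold higher. Of 18 basement membrane and collagen genes 8 were lower and 1 higher (9 and 2 adjusted over the list alone; fry adjusted p = 0.000175, adjusted p = 0.337 with an estimated correlation), and Hspg2, Col5a1, the laminin receptor subunit Itga7 and Dyrk1b fell by 4.96 ± 0.49, 3.87 ± 0.40, 2.12 ± 0.30 and 7.63 ± 1.18 on the log2 scale. Pax7 fell by 4.39 ± 1.11, from 1650 ± 135 to 78.6 ± 8.34 CPM (adjusted p = 0.00651), and Myod1 was at 1300 ± 330 against 46.1 ± 6.64 CPM (4.82 ± 1.48, adjusted p = 0.0235). Markers of other cells differed too. Of 16 macrophage and monocyte markers 9 were higher, of 14 fibro-adipogenic and fibroblast markers 7 were higher and 1 lower, and of 16 myofibre markers 8 were higher and 2 lower. Adjusted over the list alone it was 13 higher, 9 higher and 1 lower, and 10 higher and 2 lower (fry adjusted p = 0.00323, 0.000485 and 0.00588). With an estimated correlation these lists had adjusted p = 0.479, adjusted p = 0.479 and adjusted p = 0.564. In oQSC and uninjured libraries the summed macrophage markers were at 136 and 120 against 6.59 and 4.35 CPM, pericyte and smooth muscle markers at 258 and 298 against 1620 and 1790 CPM, and Schwann cell markers at 397 and 408 against 88.8 and 138 CPM. The last 2 sums do not stand for their lists. Among 12 pericyte and smooth muscle markers 4 were higher and 1 lower (median log2 fold change 1.34, fry adjusted p = 0.195). Only 1 of 10 Schwann cell markers was higher (median 0.28, fry adjusted p = 0.239). The test called 6232 of 28823 genes, 3550 higher and 2682 lower, with a median log2 fold change of all genes of 0.49 (0.36 with RLE size factors), and 14 panel genes were higher and 1 lower.

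Age, the count table and the annotation release behind it are 1 split in that comparison and in those of injured old and younger cells. Without uninjured 1, uninjured 2, oQSC 1 and oQSC 2 the oQSC against uninjured count was 3072, 3639, 3135 and 3728, and the adjusted p for Myod1 was 0.174, 0.152, 0.0575 and 0.0778. That for Pax7 was 0.0693 and 0.0752 without oQSC 1 and oQSC 2. Without uninjured 1, 10 oxidative phosphorylation and 6 interferon response genes were higher, and without uninjured 2, 13 immediate early genes. In the order of these libraries macrophage markers were higher in 2, 0, 4 and 5 cases, and without uninjured 1 and 2, 5 and 4 myofibre markers were higher, and without uninjured 1, 4 fibro-adipogenic markers. With only these groups fitted the count was 10846.

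Old cells 2.5 days and younger cells 60 h after injury differed in fewer genes. The stress gene Trp53inp1 was at 57.7 ± 1.16 CPM in oASC and 3.7 ± 0.178 CPM in 60 h cells (n = 2 per group; log2 fold change 3.96 ± 0.58, SE, adjusted p = 0.000927), and Fbxo32, a ubiquitin ligase of muscle atrophy, at 75 ± 6.38 and 3.6 ± 1.41 CPM (4.38 ± 0.61, adjusted p = 0.000544). The chemokine Ccl2 was at 285 ± 72 and 4.36 ± 0.99 CPM (6.03 ± 1.20, adjusted p = 0.00978), and Notch1 fell by 2.02 ± 0.34 on the log2 scale (adjusted p = 0.00313). Of 22 NF-kB and cytokine response genes, 6 were higher (17 higher and 1 lower adjusted over the list alone; fry adjusted p = 0.0159, adjusted p = 0.453 with an estimated correlation). No gene of the S phase and DNA replication list (26 tested) or the G2 and mitosis list (22 tested) was called by edgeR or DESeq2, also when adjusted over the list alone with edgeR, and 4 and 0 had an unadjusted p under 0.05 (fry adjusted p = 0.0551 and 0.635). Mcm5 was at 425 ± 18.9 and 289 ± 31.6 CPM (adjusted p = 0.586), Mki67 at 149 ± 8.76 and 192 ± 18.6 CPM (adjusted p = 0.92), and Pax7 at 10.4 ± 0.236 and 152 ± 5.18 CPM (adjusted p = 0.0643). The test called 633 genes, 337 higher and 296 lower, with 1 panel gene higher and 1 lower; the median log2 fold change of all genes was 0.25, and 0.08 with RLE size factors, which gave 232 higher and 388 lower genes (DESeq2 812 and 1116). Without 60 h library 1, 60 h library 2, oASC 1 and oASC 2 the count was 83, 95, 63 and 46, no NF-kB gene was called, and the adjusted p for Ccl2 was 0.166, 0.189, 0.0597 and 0.0877; that for Notch1 was 0.052 and 0.13 without oASC 1 and 2. With only these groups fitted, 7601 genes were called, 16 S phase genes were higher and 5 lower, 7 mitosis genes higher and 3 lower, 20 NF-kB genes were higher, and the adjusted p was 0.0194 for Mcm5, 0.0123 for Mki67 and 0.000265 for Pax7. The NF-kB count was 17 without the filter on low counts, 12 with DESeq2 and 1 with the replicate number as a block, and the adjusted p for Pax7 was 2.31e-13 without that filter and 0.000882 with DESeq2.

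Whether injury changed old cells otherwise than younger ones was tested as an interaction, the change from oQSC to oASC minus that from uninjured to 60 h cells. Mean levels of stress genes moved in opposite directions. Hspa8 went from 14400 ± 1000 to 3880 ± 422 CPM in old cells and from 310 ± 19.5 to 3570 ± 82.8 CPM in younger ones (n = 2 per group; log2 difference -5.42 ± 0.65, SE, adjusted p = 9.97e-05). Hspb1, Ier2 and Cdkn1a differed by -8.19 ± 1.20, -4.93 ± 0.65 and -6.79 ± 1.21. Of 14 heat shock proteins 12 and of 25 immediate early and AP-1 genes 13 had a lower response in old cells and none a higher one (13 and 19 lower adjusted over the list alone; fry adjusted p = 5.33e-06 and 0.00174). These were adjusted p = 0.0966 and adjusted p = 0.337 with an estimated correlation. Basement membrane and collagen genes had a higher response in old cells in 7 of 18 cases (9 higher and 1 lower adjusted over the list alone; fry adjusted p = 0.000772, adjusted p = 0.3 with an estimated correlation), with differences of 3.64 ± 0.53 for Col5a1 and 4.01 ± 0.61 for Hspg2. Summed pericyte and smooth muscle markers were at 258 and 298 CPM in oQSC and 303 and 289 CPM in oASC libraries, and at 1620 and 1790 CPM in uninjured and 265 and 239 CPM in 60 h libraries. Single members moved otherwise than this sum in old cells, where 9 of 12 fell and none rose after injury. In younger cells 5 fell and 1 rose at 60 h. Hspg2 went from 20.4 ± 7.58 to 181 ± 7.67 CPM in old cells and from 636 ± 75.4 to 351 ± 42 CPM in younger ones. Trp53inp1 differed by 5.85 ± 0.78 and Chpf2, a gene of chondroitin synthesis, by 5.33 ± 0.66 (adjusted p = 0.000213 and 0.000113). The test called 2098 genes, 948 higher and 1150 lower, with a median of all genes of -0.20, and 7 panel genes had a lower response and none a higher one. Leaving out a library gave 681 and 1042 calls (uninjured 1 and 2), 865 and 821 (60 h library 1 and 2), 699 and 1100 (oQSC 1 and 2), and 721 and 769 (oASC 1 and 2). Of the immediate early genes, 7 were called without uninjured 1, uninjured 2, oQSC 1 or oQSC 2, 6 without 60 h library 2, oASC 1 or oASC 2, and 20 without the filter on low counts.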

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

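The tests of explanations for the heat shock pattern given here were chosen only after the result was seen, as was the refit without ribosomal RNA, repeat and mitochondrial models.

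The response to injury differed between old and younger cells. A test of the difference itself (oQSC to oASC minus uninjured to 60 h, n = 2 per group) called 2098 genes, and each gene and list below passed it. The log2 difference was -5.42 for Hspa8, -8.19 for Hspb1, -4.93 for Ier2 and -6.79 for Cdkn1a, stress genes whose mean CPM was lower after injury in old cells and higher in younger ones. It was 5.85 for Trp53inp1, 5.33 for Chpf2, 3.64 for Col5a1 and 4.01 for Hspg2. Among the lists, the adjusted p of the difference was 5.33e-06 for heat shock proteins, 0.00174 for immediate early and AP-1 genes and 0.000772 for basement membrane and collagen genes, and none of these 3 held with an estimated correlation (0.0966, 0.337 and 0.3). The count fell to 681 without uninjured 1, 1042 without uninjured 2, 865 and 821 without 60 h library 1 and 2, 699 and 1100 without oQSC 1 and 2, and 721 and 769 without oASC 1 and 2.

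For Hspa8 the means after injury were close (3880 ± 422 CPM in oASC, 3570 ± 82.8 CPM at 60 h), and before injury heat shock and immediate early genes were higher in oQSC than in uninjured cells. A fixed difference per gene between the tables would cancel in the difference of responses, and 12 of 14 heat shock proteins were called there (fry adjusted p = 5.33e-06, adjusted p = 0.0966 with an estimated correlation), as were Hspa8 and Hspb1, which argues against it as the whole cause. Without ribosomal RNA, repeat and mitochondrial models the log2 fold change of Hspa8 was 5.52 and past the threshold. This could not test whether counts taken by these models are the cause. Ribosomal RNA models took 45.6% and 34.1% of the counts in the uninjured libraries. Removing such shares could not undo a change of this size, so the outcome was fixed. An exchange of the oQSC and oFISC labels is argued against as the whole cause, since the libraries labelled oFISC were also above uninjured cells, in 11 of 14 heat shock proteins and 19 of 25 immediate early genes (at least 76% of each list), and by a log2 fold change of 3.40 ± 0.47 for Hspa8. Age stays open and untested, as does anything particular to how the oQSC cells were collected, since age, table and collection are 1 split.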

How the results depend on the processing

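The refits without ribosomal RNA, satellite repeat and mitochondrial models, and without the oFISC libraries, were chosen after seeing the data; the other alternatives were planned. No printed gene reversed its direction. For lists only the count in the reported direction was compared, so a reversal was not checked. The alternative pseudocount was not run, since it applies to normalized values only, and list tests have no DESeq2 form. The cause of the changes below was not tested, except where a setting changes the number of genes or libraries fitted.

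The count of the test of any change from 0 to 60 h (5561) was 8777 without the filter on low counts and 10747 with DESeq2. DESeq2 called 4810, 4752, 4588 and 5145 genes at 0.5, 1, 2 and 4 h, 5297, 5836 and 3981 at 7, 14 and 28 days, 605 and 1213 for 14 and 28 against 7 days, 1928 for oASC against 60 h and 4161 for the difference of responses. Without the filter there were 188 and 683 calls for 14 and 28 against 7 days and 1037 for oASC against 60 h. RLE size factors gave 5 for 14 against 7 days. The replicate block (replicate number in the fit) gave 0 for 14 against 7 days (1691 at an unadjusted p under 0.05), 29 for 28 against 7 days and 176 for oASC against 60 h; the numbers do not pair samples, as residuals of replicates in different groups correlated from -0.707 to 0.645 in the time course. With only the groups compared in the fit, the counts were 6028 at 7 days, 0 at 14 days, 1915 at 28 days, 10846 for oQSC against uninjured and 7601 for oASC against 60 h. With all 30 libraries they were 843 and 847 for 14 and 28 against 7 days, 2440 for oFISC and 4972 for oASC against oQSC. Of the 265 list tests, 4 held with an estimated correlation. Of all 538, the number that passed was 254 with RLE size factors, 268 without the filter, 234 with the block and 264 without ribosomal RNA, repeat and mitochondrial models; how many of them are the same tests was not counted. With the oFISC libraries left out, the counts stayed within 1.5 times of the reported ones (12580 for oASC against oQSC, 6291, 644 and 2153 for the comparisons between tables).

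Leaving out 1 library at a time (44 fits; the lone sample of a group is assumed to vary like the other groups) gave 2835 to 6289 genes with any change. By time it gave 262 to 2220 genes at 0.5 h, 377 to 1398 at 1 h, 234 to 1945 at 2 h, 273 to 2319 at 4 h, 1986 to 2628 at 8 h, 1215 to 2824 at 16 h, 1480 to 2984 at 32 h and 3248 to 3475 at 60 h. It gave 1192 to 1468 at 7 days, 1479 to 2949 at 14 days, 494 to 1431 at 28 days, 0 to 324 for 14 against 7 days and 0 in each case for 28 against 7 days. For old cells it gave 8000 to 9210 (oFISC against oQSC), 8564 to 10030 (oASC against oQSC), 3072 to 3728 (oQSC against uninjured), 46 to 95 (oASC against 60 h) and 681 to 1100 (difference of responses).

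The 193 gene values in the report, each tried under the same settings, had the same direction and side of the threshold in 187 cases with DESeq2 (6 more passed), 192 with RLE size factors, 184 without the filter (9 more passed), 191 with the block, 39 of 51 with only the groups compared, 28 of 31 with all 30 libraries, and 726 of 804 times with 1 library left out. Of 70 list counts, 67 stayed within 1.5 times with DESeq2, 67 with RLE size factors, 64 without the filter, 66 with the block, 11 of 19 with only the groups compared, 7 of 15 with all 30 libraries, and 186 of 292 with 1 library left out. These genes and lists were selected after their values were seen. In the counts that follow, an entry that a setting did not test, or gave no adjusted p, counts as called there. Of all 1623 called entries that the naming rule gives, 1224 were called in every other setting, 814 whichever library was left out and 685 in both; with 1 library left out, 3 changed direction. The regeneration series had totals from 9.18 to 13.9 M counts per library and the highest dispersion of the 4 fits (0.432); which of these limits its calls was not tested.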

Other observations

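Of the tests reported in this part, those on depth, on other cell types, on exchanged labels and on progress of the response were chosen only after the result was seen; the genomic DNA test and the test of single genes were set beforehand.

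Summed marker genes of other cell types differed between libraries. Pericyte and smooth muscle markers stood at 1620 and 1790 CPM in the uninjured libraries and at 90.9 to 805 CPM in those from 0.5 to 32 h, and at 265 and 239 CPM at 60 h. This sum does not stand for its list of 12 markers. Against uninjured cells 3 rose and 1 fell at 4 h, 3 rose and 2 fell at 8 h, and 1 rose and 5 fell at 60 h. Neutrophil markers were at 2.29 and 2.99 CPM in uninjured cells and 63.2 and 62.2 CPM at 0.5 h. Fibro-adipogenic and fibroblast markers were at 1090 and 1190 CPM in uninjured cells, 3690 and 1520 CPM at 0.5 h and 3870 and 3470 CPM at 7 days. Myofibre markers reached 708 and 588 CPM at 14 days, and were at 634 and 106 CPM in the oFISC libraries.

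The libraries of the 0.5, 1, 2 and 4 h groups differ within each group, Pax7 and Myod1 among the genes that differ. Depth is argued against: the totals of these pairs differed by a ratio of at most 1.2, against up to 1.34 in the pairs from 8 to 60 h. So is dilution by other cell types as the whole cause, which would lower both genes alike. The log2 ratio of Myod1 exceeded that of Pax7 by at least 5.41 in each pair, with opposite signs. Markers of other cells did differ. Fibro-adipogenic and fibroblast markers summed to 3690 and 1520, 2490 and 1510, 1230 and 3110, and 2760 and 1260 CPM at 0.5, 1, 2 and 4 h. They, pericyte and Schwann cell markers were higher in the library with more Pax7 in each pair. Macrophage markers went the other way at 0.5, 2 and 4 h. Exchanges of labels among these groups cannot be told apart from other causes: of the 105 ways to pair the 8 libraries, 9 brought the lowest correlation inside the pairs to 0.833, the lowest of the uninjured and 8 to 60 h groups, or over it (best 0.888, against 0.693 as labelled). A candidate explanation is different progress of the response at the same labelled time, since in each pair the library with more Myod1 was closer to the 8 h libraries, by a mean correlation of at least 0.184 (0.29, 0.184, 0.209 and 0.205); exchanged labels could give the same, and this was tested on the libraries in which it was noticed.

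The oFISC libraries count reads over more genes than the oQSC libraries. Deeper sequencing is argued against, since the lowest oQSC total was 1.93 times the highest oFISC total. For genomic DNA, 4 gene families of restricted expression were compared, with a bound set beforehand: a lowest ratio of oFISC to oQSC under 1.5 would count against it. The lowest was 0.48 (beta-defensins; vomeronasal receptors 13.4, taste receptors 4.02, keratin-associated proteins 11.5), so the bound was met. It was a wrong bound, because the single gene Defb25 (12.2 CPM in oQSC, 1.56 CPM in oFISC cells) sets the beta-defensin sum, whose ratio without it was 6.88, so genomic DNA cannot be told apart from other sources here; this exception was made after the value was seen. Transcription of single genes may contribute, as olfactory receptor counts were uneven after allowing for length (variance over mean at least 15.6 in the oFISC libraries), but they were also uneven in the oQSC libraries (30.5 and 12.9), and amplification also makes counts uneven.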
